A study of Homo sapiens with 4 samples.

How the data were processed

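Total RNA of A549 cells was measured on 4 arrays, 2 after transfection of a miR-7 precursor and 2 after a miR-NC control precursor. Per the labels' protocols, RNA was extracted 24 hours after transfection with TRIzol and an RNeasy column and labelled with biotin by standard Affymetrix procedures. The deposited values are intensities on a linear scale, made with MAS5 per the submitters' processing notes. The software version and target value are not given in the sources used here. In the values, the mean of each array without its lowest and highest 2% was 500.1. Such scaling gives every array the same trimmed mean and so removes any change of total mRNA per cell. Detection calls were not used here, and array pairs shared at most 1 identical value, so no array was a copy of another.

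From these values, 62 control probe sets of 54675 were left out and log2(value + 16) was taken, which understates changes of dim genes. The 27307 probe sets whose mean over the 4 arrays reached the median (an intensity of about 89.5) were kept. Gene names came from the annotation of the array, where 41097 probe sets had 1 symbol, 1801 had several and 11777 were unnamed here. Symbols were looked up by gene number in the RefSeq gene table of GRCh38.p14, where 41043 matched and 0 changed. No coordinates are given, since no genome build was named for the array. A gene took the probe set with the highest mean, among those with 1 symbol, which left 12283 genes. In 5933 genes with at least 2 kept probe sets, these could disagree.

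Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on mean level), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. The trend shares information on spread between genes of like level and gave 11.5 prior degrees of freedom. The median SE was 0.36 in the lower part of the genes split at the median level and 0.14 in the upper part, so brighter genes were measured more precisely. The 22 gene lists were fixed before the data were examined, as were the tests, the naming rule and the alternatives, except where said otherwise. Lists with at least 5 measured genes (20 of 22) were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. With an estimated correlation, camera has only the residual degrees of freedom of the 4 arrays, so it could hardly pass any list. List members without a kept probe set, and some others, were not analysed here.

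The naming rule took EGFR, the 12 called genes with the most negative and the 12 with the most positive log2 change whose groups did not overlap, and up to 4 called members of each list by size of change. Where a list had fewer than 2 called members, its largest changes were given as values, up to 2. A further gene in the rule is not reported here. AKT1, CCL2, NFKB1, PDPK1, SC5D and TNK2 were named after their values were seen, as were the genes of the closing section. The labels describe the arrays of a group as biological replicates and do not say that equal replicate numbers mark a shared day, so no block was fitted.

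Alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no level filter, a filter at the 75th percentile, the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, no variance trend, the replicate number as a block, other thresholds and leaving out each array. A planned test of genes with a match to the miR-7 seed was not run, since no transcript sequences were used here. In simulated data of 12283 genes, the steps recovered 35% of genes changed by 1 and 61% of those changed by 2 (log2 scale). Of 105 calls, 9 were false. Simulated genes were independent and their spread followed the trend and prior that limma assumes, so the simulation does not check that trend. Only 100 genes of each size were changed, against 1703 called in the data, so these shares need not hold there. In a second simulation only 1 list, the published miR-7 targets, was shifted, with every member moved by the same amount. Camera recovered it at the preset correlation, and 0 of the other genes were called. Genes were independent there too, so it does not test lists whose members move together, or lists whose members change by unlike amounts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.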

Results

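Transcript levels were profiled in A549, an established epithelial line from a lung carcinoma, after transfection of a precursor of the microRNA miR-7 or of a control precursor termed miR-NC. Total RNA was collected 24 hours after transfection, and each group held 2 arrays that the labels call biological replicates. The comparison asks what miR-7 does to transcript levels in cancer cells, with signalling by the epidermal growth factor receptor EGFR as the stated subject. Median intensity was 119.7 and 99.5 on the miR-7 arrays and 97.0 and 105 on the miR-NC arrays. The 1st percentile was 8.17 on miR-7 replicate 1 and 2.99 to 3.43 on the other arrays. Across genes, which are not independent replicates, Pearson's r was 0.967 within miR-7, 0.974 within miR-NC and 0.945 to 0.957 between the groups over the genes tested. Over all probe sets it was 0.933, 0.943 and 0.924 to 0.936, and there miR-7 replicate 2 correlated at 0.936 with each miR-NC array, above its 0.933 with miR-7 replicate 1. With 2 arrays per group, the number of arrays limits the precision of every value given here.

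EGFR, the receptor tyrosine kinase named in the title of the series, was 3.13-fold lower with miR-7 on the log2(value + 16) scale. Its mean intensity was 2511 ± 62 with miR-7 and 7904 ± 742 with miR-NC (SD, n = 2). The log2 change was -1.65 (SE 0.12, 95% interval -1.90 to -1.39, limma adjusted p = 1.39e-06). EGFR had 9 probe sets, of which 5 passed the level filter. Adjusted over all probe sets kept, the 3 brightest changed by -1.65, -1.65 and -1.54 (adjusted p = 1.16e-05, 0.000108 and 1.77e-05). The dimmer EGFR probe sets gave -2.35 (adjusted p = 0.0629) and 0.30 (adjusted p = 0.808), neither past the threshold. Without a trend of variance on level, the EGFR change stayed at -1.65 but its adjusted p was 0.0789, the highest over all alternatives. The lowest, 4.35e-49, came from the replicate block, where infinite prior degrees of freedom set each gene's own spread aside.

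Of 12283 genes tested, 972 were lower and 731 higher with miR-7 (limma, adjusted p under 0.05), and 3306 had an unadjusted p under 0.05. The median change of the called genes was -0.79 for those lower and 0.70 for those higher, against 0.01 over all genes. At least a 2-fold change was reached by 315 of the lower and 136 of the higher genes, and at least a 4-fold change by 23 and 6. All 1703 called genes had groups that did not overlap, as did 54.1% of all genes, where chance gives 33.3%. The 3' to 5' intensity ratio of the ACTB control was 1.50 and 1.60 on the miR-7 arrays and 1.23 and 1.27 on the miR-NC arrays. Neither other control was higher on both miR-7 arrays. GAPDH gave 0.973 and 0.970 against 0.979 and 1.01, and the interferon-response control 10.3 and 10.5 against 6.17 and 11.4. Without the variance trend, limma called 0 genes lower and 0 higher, with 2575 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0789. Without miR-7 replicate 2, 899 genes were called lower and 437 higher, and 1095 of these calls were also made with every array.

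**Figure D1:**
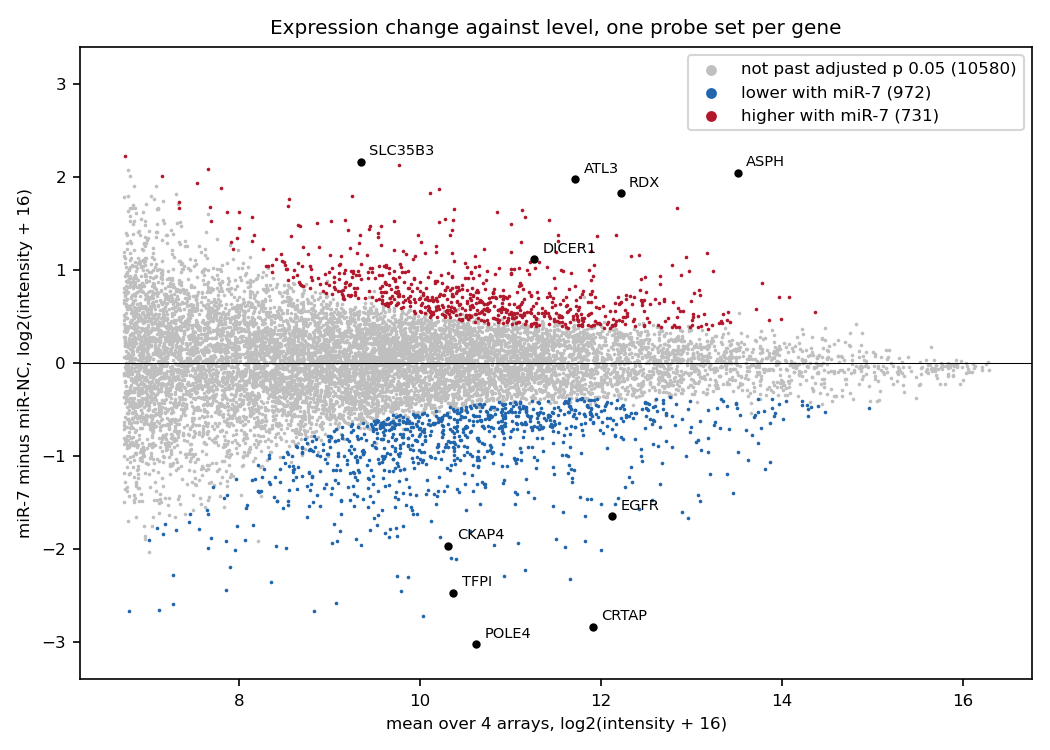
Each point is a gene, placed by its mean over the 4 arrays (x axis, log2(intensity + 16)) and its change, miR-7 minus miR-NC (y axis, same scale). Blue points are the 972 genes called lower, red points the 731 called higher and grey points the rest, with EGFR at -1.65 among the named genes in black.

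Among the genes lower with miR-7, POLE4, a subunit of DNA polymerase epsilon, was 8.12-fold lower on the log2(value + 16) scale, which damps the change of dim genes (541 ± 109 against 4468 ± 12, SD, n = 2; adjusted p = 1.67e-07). CRTAP, which takes part in collagen prolyl hydroxylation, was 7.14-fold lower (1435 ± 209 against 10307 ± 894, SD, n = 2; adjusted p = 8.58e-08). SLC35A4, of a family of nucleotide sugar transporters, changed by -2.72 (SE 0.17), the ubiquilin UBQLN4 by -2.67 (SE 0.33), and the cannabinoid receptor interacting protein CNRIP1 by -2.66 (SE 0.63). EXTL3, a glycosyltransferase of heparan sulfate synthesis, changed by -2.66 (SE 0.58), PCNX3 by -2.59 (SE 0.51), and PIGH, of the first step of GPI anchor synthesis, by -2.58 (SE 0.25). TFPI, the inhibitor of the tissue factor pathway of coagulation, changed by -2.47 (SE 0.15). CYB561A3, a cytochrome b561 family member, changed by -2.46 (SE 0.17), the receptor tyrosine kinase TYRO3 by -2.45 (SE 0.48) and DYM by -2.36 (SE 0.30). Every kept probe set of POLE4 and CRTAP was lower and passed the threshold. The other kept probe set of UBQLN4 gave 0.05 (adjusted p = 0.975), that of TYRO3 gave -0.999 (adjusted p = 0.334), and those of TFPI gave -0.92, 0.39 and 1.17, none past the threshold. With the mean of probe sets, TFPI changed by -0.45 (adjusted p = 0.172) and UBQLN4 by -1.31 (0.0276). CNRIP1 was no longer called without miR-NC replicate 1 (-2.43) or 2 (-2.90), nor EXTL3 (-2.53) and PCNX3 (-2.42) without miR-NC replicate 1. These changes stayed about as large.

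Among genes higher with miR-7, ASPH, an aspartate beta-hydroxylase, had a mean of 24004 ± 4654 against 5747 ± 565 (SD, n = 2; 4.14-fold, adjusted p = 1.15e-06). ATL3, an atlastin GTPase of the endoplasmic reticulum, was 3.94-fold higher (adjusted p = 6.79e-07). RDX, which encodes radixin, a linker of actin to the plasma membrane, was 3.54-fold higher (8945 ± 142 against 2518 ± 198, SD, n = 2; adjusted p = 6.18e-07). The nucleotide sulfate transporter SLC35B3 changed by 2.17 (SE 0.20), the xylosyltransferase GXYLT1 by 2.13 (SE 0.20), and the histone gene regulator HINFP by 2.09 (SE 0.41). RAB8B, a small GTPase of membrane traffic, changed by 1.87 (SE 0.16), NEURL1B by 1.88 (SE 0.39) and DENND6A by 1.82 (SE 0.16). PRELID3A changed by 2.23 (SE 0.68), the neuronal calcium sensor HPCA by 2.01 (SE 0.58) and the zinc finger gene ZNF165 by 1.94 (SE 0.53). On miR-NC replicates 1 and 2, intensities were 59.6 and 15.8 for PRELID3A, 89.9 and 30.5 for HPCA, and 38.2 and 148.6 for ZNF165. Apart from the last, these lay near or below the level filter, so the sizes of these changes depend on the pseudocount. HPCA changed by 2.32 at a pseudocount of 1 and by 1.46 at 64, and ZNF165 by 2.18 and 1.48. PRELID3A was not among the genes tested at a pseudocount of 1. The other kept probe set of ATL3 gave 0.01 (adjusted p = 0.988), and 1 of the other kept probe sets of RAB8B gave 0.15 (adjusted p = 0.737). Of the other kept ASPH probe sets, 3 passed at 1.66, 0.47 and 0.48 (adjusted p = 0.000724, 0.0473 and 0.0374) and 3 did not, at 0.47, 0.32 and 0.18 (0.121, 0.181 and 0.751). ASPH changed by 0.81 (adjusted p = 0.00563), ATL3 by 0.99 (0.00287) and RAB8B by 1.15 (0.00273) with the mean of probe sets, and ASPH by 0.47 (0.0320) without probe sets ending in _x_at or _s_at. PRELID3A was no longer called without miR-7 replicate 1, miR-7 replicate 2 or miR-NC replicate 2, where it changed by 1.61 to 2.25. It also did not pass after quantile normalization (2.10, adjusted p = 0.0604), without the level filter (2.23, 0.0508) or with the mean of probe sets (2.23, 0.0619). At a pseudocount of 64 PRELID3A changed by 1.49 (adjusted p = 0.0381). HPCA lost its call without the same 3 arrays (adjusted p 0.0635 to 0.177), and ZNF165 without miR-7 replicate 1, miR-7 replicate 2 or miR-NC replicate 1 (adjusted p 0.0618 to 0.147, with 1.14 without the last).

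**Figure D2:**
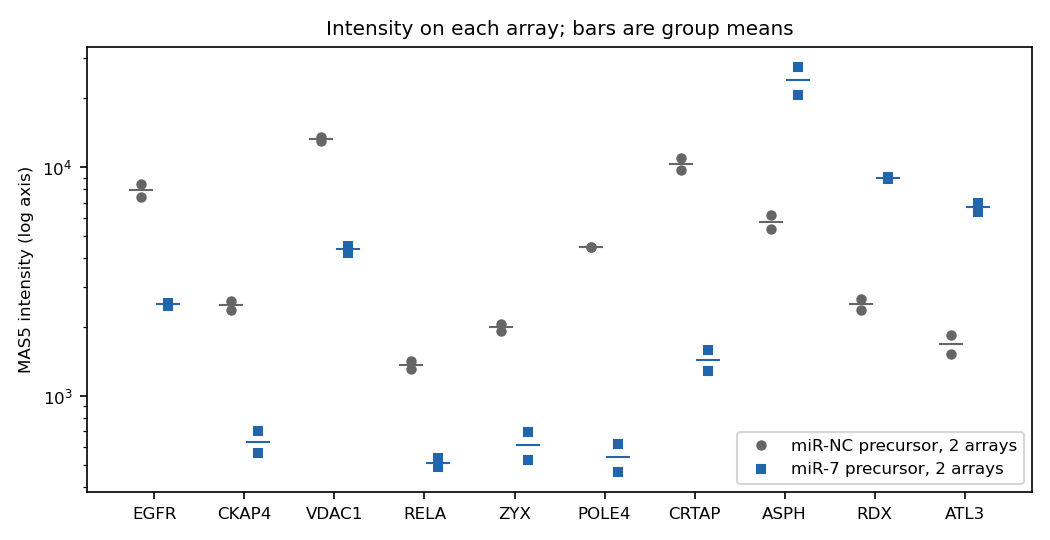
MAS5 intensity (log axis) of 10 genes on each array, with squares for the 2 miR-7 arrays, circles for the 2 miR-NC arrays and bars for group means. EGFR lies at a mean of 2511 with miR-7 and 7904 with miR-NC, and ASPH at 24004 and 5747.

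Of 22 measured genes published as miR-7 targets, 10 were lower, 0 higher and 12 not past the threshold. Their median change was -0.40 (camera adjusted p = 0.000459 at the preset correlation, but adjusted p = 0.695 with an estimated correlation). The estimated correlation of these genes was -0.04, below the preset, so the higher p came from the few degrees of freedom of that form. The examples were CKAP4, a membrane protein of the endoplasmic reticulum (-1.96, SE 0.16), EGFR, the mitochondrial channel VDAC1 (-1.60, SE 0.11) and the NF-kB subunit RELA (-1.39, SE 0.17). At -1.54, the kinase TNK2 did not pass the threshold (SE 0.50, adjusted p = 0.0567). Over arrays left out, TNK2 ran from -2.27 without miR-7 replicate 2, where it passed (adjusted p = 0.00397), to -0.82 without miR-7 replicate 1 (0.194). TNK2 gave -0.81 with the mean of probe sets, and -0.074 without probe sets ending in _x_at or _s_at. It passed after median centring (0.0368), and over all alternatives its adjusted p ran from 0.00397 to 0.966. Adjusted over the list alone, 11 were lower and 0 higher. The list is not independent evidence of direction, since it holds targets drawn from studies of miR-7 that may include these samples. Of 15 measured genes of the cytoskeleton and motility, 7 were lower, 0 higher and 8 not past the threshold, with the same counts adjusted over the list alone. Their median was -0.43 (camera adjusted p = 0.000496 at the preset correlation, but adjusted p = 0.695 with an estimated correlation). The estimated correlation of the cytoskeleton genes was 0.34, so for them both the correlation and the few degrees of freedom raised the unadjusted camera p, to 0.211. Those lower included ZYX, which encodes the focal adhesion protein zyxin (-1.70, SE 0.17), the actin capping gene CAPZA1 (-1.45, SE 0.11), the profilin PFN2 (-1.42, SE 0.11) and PXN, which encodes paxillin (-0.95, SE 0.14). By fry, which tests a list's own movement, the adjusted p was 0.0266 for the published targets and 0.0961, not past the threshold, for the cytoskeleton genes. Without probe sets ending in _x_at or _s_at, camera gave an adjusted p of 0.140 and 0.151, and over all alternatives, the estimated correlation included, each ran from 7.37e-05 to 0.695. The other 18 lists tested did not pass the threshold, in camera or in fry.

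**Figure D3:**
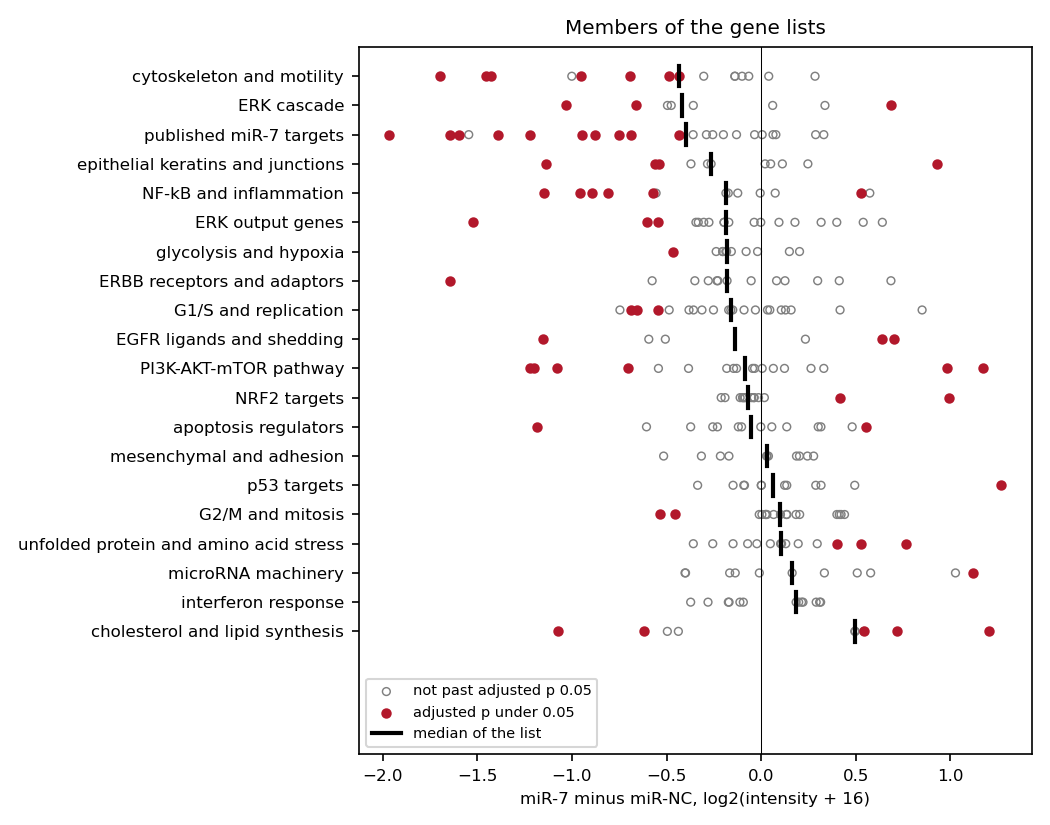
Change of each list member, miR-7 minus miR-NC (x axis, log2(intensity + 16)), for the 20 lists tested, with filled points for called members and bars for list medians. The cytoskeleton and motility list has a median of -0.43 and the published miR-7 targets -0.40.

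Among receptors and adaptors of the ERBB family, EGFR was lower and the other 12 of 13 measured members did not pass, PLCG1 being nearest in size at 0.69 (adjusted p = 0.0700, 0.0473 with the level filter at the 75th percentile, and 0.0444 without miR-7 replicate 2, at 0.88, against 0.29 with the mean of probe sets). Of 6 genes for EGFR ligands and their shedding, the ligand gene TGFA was lower (-1.15, SE 0.23), and the protease ADAM17 (0.70, SE 0.12) and the ligand gene NRG1 (0.64, SE 0.12) were higher. NRG1 turned to -0.23 with the mean of its probe sets and to -0.31 without probe sets ending in _x_at or _s_at, not past the threshold in either. Of 8 measured genes of the ERK cascade, MAP2K2 (-1.03, SE 0.13) and HRAS (-0.66, SE 0.13) were lower and MAP2K1 (0.69, SE 0.13) higher. Of 18 genes known to respond to ERK, ETV4 (-1.52, SE 0.35), FOSL1 (-0.60, SE 0.17) and CCND1 (-0.54, SE 0.14) were lower and 0 higher, with 1 higher at an unadjusted p under 0.05. In the PI3K, AKT and mTOR list of 18, 4 were lower and 2 higher. Those lower were PIK3CD (-1.22, SE 0.38), AKT2 (-1.20, SE 0.15), PIK3CB (-1.08, SE 0.18) and AKT1 (-0.70, SE 0.14), and those higher were PIK3R1 (1.17, SE 0.31) and PDPK1 (0.98, SE 0.16). Adjusted over the list alone, the counts were the same for the ERBB, ERK cascade and PI3K lists, with 2 lower and 2 higher for the ligands and 4 lower for the ERK responsive genes. The median and mean of the ligand list were -0.14 and -0.11, while camera placed the list upwards (adjusted p = 0.894).

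Several of these calls were lost with an array left out or with other probe sets. ETV4 was not called without miR-NC replicate 1 or 2 (adjusted p 0.0560 to 0.0771), FOSL1 and CCND1 without miR-7 replicate 1 or miR-NC replicate 2 (0.0714 to 0.188 and 0.0541 to 0.181). Without miR-7 replicate 1, FOSL1 changed by -0.38 and CCND1 by -0.35, and without miR-NC replicate 2 FOSL1 changed by -0.39. PIK3CD was not called without miR-7 replicate 2, miR-NC replicate 1 or miR-NC replicate 2 (0.0823 to 0.177), with -0.68 without miR-7 replicate 2, nor PIK3R1 without miR-7 replicate 1 or miR-NC replicate 2 (0.0571 to 0.170). With the mean of probe sets, AKT2 (-0.60, adjusted p = 0.178), PIK3CB (-0.47, 0.269), PIK3CD (-0.59, 0.207), PIK3R1 (0.89, 0.118), PDPK1 (0.72, 0.116) and FOSL1 (-0.60, 0.0654) did not pass. PIK3R1 (0.82, 0.126) and PDPK1 (0.54, 0.195) also did not pass without probe sets ending in _x_at or _s_at, nor PIK3CD without the level filter (0.0576).

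In the cell cycle lists, 3 of 21 genes of the G1/S transition and replication were lower, namely CCNE1 (-0.69, SE 0.13), CDK6 (-0.66, SE 0.15) and CCND1 (-0.54, SE 0.14), and 0 were higher, with 1 higher at an unadjusted p under 0.05. Of 17 genes of G2/M and mitosis, PLK1 (-0.53, SE 0.13) and CDC20 (-0.46, SE 0.11) were lower and 0 higher, with 3 higher at an unadjusted p under 0.05. Adjusted over the list alone, the G1/S counts were the same and the G2/M counts were 2 lower and 3 higher. Of 12 measured p53 targets, ZMAT3, an RNA-binding zinc finger gene, was higher (1.27, SE 0.27) and 0 were lower, with 1 lower at an unadjusted p under 0.05. Without miR-NC replicate 2, ZMAT3 changed by 0.80 (adjusted p = 0.00417). RRM2B, also a p53 target, gave 0.49 (adjusted p = 0.102). Of 14 apoptosis regulators, the initiator caspase CASP9 was lower (-1.18, SE 0.26) and PMAIP1 higher (0.55, SE 0.13). The p53 and apoptosis counts were the same adjusted over the list alone. CCND1 lost its call without miR-7 replicate 1 (-0.35) or miR-NC replicate 2 (adjusted p 0.0541 to 0.181), CDK6 without miR-7 replicate 2 (0.0892), PLK1 without miR-7 replicate 1 or miR-NC replicate 1 (0.0617 to 0.106) and CDC20 without miR-7 replicate 1 or 2 (-0.45 and -0.46, adjusted p 0.0519 to 0.0555). CASP9 lost its call without miR-NC replicate 1 (0.0510) and PMAIP1 without miR-7 replicate 1 (0.0935). With the mean of probe sets, CDK6 (-0.22, adjusted p = 0.591), ZMAT3 (0.58, 0.0987) and PMAIP1 (0.35, 0.0935) did not pass.

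Of 13 NF-kB and inflammation genes, 5 were lower and 1 higher, with a median of -0.19 (camera adjusted p = 0.182). Those lower were RELB (-1.15, SE 0.22), the chemokine CXCL3 (-0.96, SE 0.27), the inhibitor NFKBIA (-0.89, SE 0.15), NFKB2 (-0.81, SE 0.18) and NFKB1 (-0.57, SE 0.14), and the chemokine CCL2 was higher (0.53, SE 0.13). Without miR-NC replicate 1 the list passed, with an adjusted p of 0.0360, in a range over alternatives of 0.0360 to 0.695. With every array the list had a camera adjusted p = 0.695 (unadjusted p = 0.144) with an estimated correlation, a form with few degrees of freedom. CXCL3 was not called without miR-7 replicate 1 or miR-NC replicate 2 (adjusted p 0.0905 to 0.311), NFKB2 without miR-7 replicate 1 (0.0530) or probe sets ending in _x_at or _s_at (-0.51, 0.220), and NFKB1 without miR-7 replicate 1 or 2 (-0.55 and -0.59, adjusted p 0.0501 to 0.0678). CCL2 was not called without miR-7 replicate 1, miR-7 replicate 2 or miR-NC replicate 2 (0.0504 to 0.0911). Of 13 interferon response genes, limma called 0, and 0 had an unadjusted p under 0.05, with OAS1 at -0.37 (adjusted p = 0.229) and IRF9 at 0.31 (adjusted p = 0.498). OAS1 ran from -0.52 without miR-7 replicate 1 to -0.23 without miR-7 replicate 2, gave -0.076 with the mean of probe sets and turned to 0.22 without probe sets ending in _x_at or _s_at. IRF9 ran from -0.053 without miR-NC replicate 2 to 0.68 without miR-NC replicate 1. Adjusted over the list alone, the counts for both lists were the same.

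Among 11 epithelial keratin and junction genes, the keratins KRT7 (-1.14, SE 0.12), KRT8 (-0.56, SE 0.12) and KRT19 (-0.54, SE 0.12) were lower and the tight junction gene TJP1 was higher (0.93, SE 0.11). KRT7 gave -0.22 with the mean of its probe sets (adjusted p = 0.464) and turned to 0.33 without probe sets ending in _x_at or _s_at (adjusted p = 0.540). TJP1 changed by 0.57 with the mean of probe sets (adjusted p = 0.0220). KRT8 lost its call without miR-NC replicate 1 (adjusted p = 0.0589) and KRT19 without miR-7 replicate 2 (0.0542). Of 11 mesenchymal and adhesion genes, limma called 0, with 1 lower at an unadjusted p under 0.05. Vimentin, VIM, gave -0.32 (adjusted p = 0.203) and the cadherin CDH2 -0.52 (adjusted p = 0.186). After quantile normalization VIM passed at -0.22 (adjusted p = 0.0395), and without miR-7 replicate 2 at -0.42 (0.0329). CDH2 passed without miR-7 replicate 1 at -0.93 (adjusted p = 0.0116), and over arrays left out it ran from there to -0.10, the value without miR-7 replicate 2, and it gave -0.27 with the mean of probe sets. The mesenchymal list had a median of 0.03 and a mean of -0.02, and camera placed it downwards (adjusted p = 0.961). Both lists had the same counts adjusted over the list alone.

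Of 14 genes of the unfolded protein and amino acid stress responses, DNAJB9 (0.76, SE 0.13), DDIT3 (0.53, SE 0.13) and HERPUD1 (0.40, SE 0.12) were higher and 0 lower, with 0 lower also at an unadjusted p under 0.05. Of 14 NRF2 targets, the cystine transporter SLC7A11 (0.99, SE 0.12) and the malic enzyme ME1 (0.41, SE 0.12) were higher and 0 lower, with 0 lower at an unadjusted p under 0.05. The NRF2 list had a median of -0.07 and a mean of 0.03, and camera placed it upwards (adjusted p = 0.971). Of 10 cholesterol and lipid synthesis genes, IDI1 (1.20, SE 0.18), SQLE (0.72, SE 0.14) and SC5D (0.54, SE 0.16) were higher, and DHCR7 (-1.07, SE 0.19) and the fatty acid synthase FASN (-0.62, SE 0.16) lower. Their median was 0.50 and their mean 0.14 (camera adjusted p = 0.684), and adjusted over the list alone 4 were lower and 6 higher. Counts adjusted over the list alone were the same for the stress and NRF2 lists. DDIT3 was not called without miR-7 replicate 2 (adjusted p = 0.126), nor HERPUD1 without miR-7 replicate 1 or miR-NC replicate 1 (0.111 to 0.256), with the mean of probe sets (0.0585) or after median centring (0.0535). ME1 was not called without miR-7 replicate 2, miR-NC replicate 1 or miR-NC replicate 2 (0.0812 to 0.152) or after median centring (0.0578). SC5D was not called without miR-7 replicate 1, miR-7 replicate 2 or miR-NC replicate 2 (0.0617 to 0.176), nor FASN without miR-7 replicate 2 or miR-NC replicate 1 (0.114 to 0.137) or with the mean of probe sets (-0.098, adjusted p = 0.803). Without probe sets ending in _x_at or _s_at, DNAJB9 (0.37, adjusted p = 0.501) and IDI1 (0.40, 0.366) did not pass. IDI1 changed by 0.73 (adjusted p = 0.0183) and SLC7A11 by 0.65 (0.00561) with the mean of probe sets.

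The gene for DICER1, the ribonuclease that cuts microRNA precursors, was 2.17-fold higher with miR-7 (3608 ± 1 against 1652 ± 40, SD, n = 2; adjusted p = 3.96e-05). It was the called member among 11 measured genes of the microRNA machinery, with 0 lower and 1 lower at an unadjusted p under 0.05. The argonaute AGO4 gave 1.03 without passing (adjusted p = 0.116). Of 11 glycolysis and hypoxia genes, the aldolase ALDOA was lower (-0.47, SE 0.14) and 0 higher, with 0 higher at an unadjusted p under 0.05, and LDHA gave -0.24 (adjusted p = 0.401). LDHA passed without miR-7 replicate 2 at -0.41 (adjusted p = 0.0366), and gave -0.066 without miR-7 replicate 1 and -0.15 after quantile normalization. ALDOA was not called without miR-7 replicate 1, miR-NC replicate 1 or miR-NC replicate 2 (adjusted p 0.111 to 0.198), with the mean of probe sets (0.0566), after median centring (0.105) or without the level filter (0.0505). Counts adjusted over the list alone were the same for both lists.

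Markers of cell types that the culture should lack were mostly not among the genes tested. Of leukocyte markers 1 was measured, CD79A, at -0.29 (adjusted p = 0.780), and of fibroblast and endothelial markers 4, among them PDGFRB at -0.89 (adjusted p = 0.418) and PECAM1 at -0.50 (adjusted p = 0.593). Without miR-7 replicate 1 PDGFRB gave -0.015, CD79A -1.03 and PECAM1 -1.04, and without miR-7 replicate 2 they gave -1.78, 0.46 and 0.029. PDGFRB gave -0.60 at a pseudocount of 64, and CD79A -0.11 with the mean of probe sets. Limma called 0 in either list, also adjusted over the list alone, and 0 had an unadjusted p under 0.05.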

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

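The comparison of control ratios was chosen after the data were seen. The 3' to 5' intensity ratio of the ACTB control probe sets, which no gene comparison used, averaged 1.55 on the miR-7 arrays and 1.25 on the miR-NC arrays. It was 1.50 and 1.60 against 1.23 and 1.27, so both miR-7 arrays lay above both controls. For GAPDH the ratio was 0.973 and 0.970 with miR-7 against 0.979 and 1.01, and for the interferon-response control 10.3 and 10.5 against 6.17 and 11.4. No explanation of the difference, technical or biological, was tested.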

How the results depend on the processing

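Every alternative here was planned. EGFR stayed lower in each (-1.74 to -1.55 over arrays left out) and passed except without the variance trend (-1.65, adjusted p = 0.0789). There 0 genes were lower and 0 higher, and 0 of 81 named called genes passed. Prior degrees of freedom were 2.26 there against 11.5, and prior variances differed too, so the cause was not separated. With at least a 2-fold change as well, 315 were lower and 136 higher, and by 2-fold change with groups apart and no test 456 and 262. Without probe sets ending in _x_at or _s_at, 602 were lower among 9484 genes tested. With the mean of probe sets 474 were higher, a cause not tested. Same-numbered deviations correlated at 0.07 over genes, which gives no sign that equal replicate numbers pair the arrays but cannot exclude it. The replicate block gave 1571 lower and 1305 higher, with infinite prior degrees of freedom, and there CDH2 (0.0212), PLCG1 (0.0172), RRM2B (0.0380) and TNK2 (0.00643) passed too. Leaving out each array gave 774 to 899 lower and 437 (without miR-7 replicate 2) to 726 higher, with the lone array assumed to vary like the other group. Without either miR-NC array the prior was infinite too. Of the 81 named called genes, 50 kept their call without each array and 31 lost it. Shifted lists numbered 0 with an estimated correlation, 1 by fry, 0 without probe sets ending in _x_at or _s_at, and 2 to 3 over arrays left out. Camera used no variance trend, so leaving it out says nothing about lists.

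Some directions reversed, causes not tested. NRG1 gave -0.23 with the mean of probe sets. Without probe sets ending in _x_at or _s_at, NRG1 gave -0.31, KRT7 0.33 and OAS1 0.22. Over arrays left out, CD79A ran from -1.03 to 0.46, PECAM1 from -1.04 to 0.029 and IRF9 from -0.053 to 0.68. Lists whose camera direction turned passed in neither setting. Their adjusted p was 0.975 for mesenchymal genes after quantile normalization and 0.986 for apoptosis at the 75th percentile filter. Without the level filter it was 0.802 for ligands and interferon and 0.836 for NRF2. With the mean of probe sets it was 0.484 (ligands), 0.987 (interferon), 0.996 (mesenchymal) and 0.950 (NRF2). Without probe sets ending in _x_at or _s_at it was 0.698 for ligands and keratins, and with the replicate block 0.978 for ligands and 0.967 for NRF2. Lists that turned over arrays left out ranged from 0.624 to 0.995 (apoptosis), 0.320 to 0.704 (interferon), 0.678 to 0.995 (mesenchymal), 0.0836 to 0.755 (glycolysis), 0.755 to 0.984 (ligands) and 0.317 to 0.986 (NRF2). In all, 1053 of 1241 values of named genes kept direction and side of the threshold. So did 235 of 260 of lists, with the variance trend setting, the estimated correlation and fry left out. Named genes that a setting dropped from the test are not among the 1241 values. They dropped out mostly without probe sets ending in _x_at or _s_at and at the 75th percentile filter. In the main fit 2 of 20 lists passed, so most list values kept were of lists that did not pass. The seed-site test and its alternatives were not run. Fewer genes were called at low level, with 27 lower and 15 higher in the lowest of 4 bins of genes by level. The next bins had 179 and 110, 402 and 297, and in the highest 364 and 309. The median SE was 0.53 in the lowest bin and 0.13 in the highest.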

Other observations

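The test of symbol families and the choice of genes below followed sight of the data, while the test of microRNA competition was set before its result. Of 18 measured IFT genes, named for intraflagellar transport, the traffic of proteins along cilia, 5 were higher, 0 lower and 13 not past the threshold (limma; the median change was 0.37). With an estimated correlation, camera gave each of 146 families of like symbols an adjusted p of 0.9996. That form has few degrees of freedom and told no family apart. At the preset correlation, camera gave the IFT family an adjusted p of 0.0198. Those higher were IFT80 (1.36, SE 0.21), IFT22 (0.78, SE 0.12), IFT57 (0.73, SE 0.15), IFT88 (0.70, SE 0.21) and IFT43 (0.54, SE 0.13), while IFT172 gave -0.61 (adjusted p = 0.259). At the preset correlation it was the single family past the threshold, with 0.0153 after quantile normalization and 0.0246 after median centring. The adjusted p was 0.0695 without miR-7 replicate 1, 0.0654 without miR-7 replicate 2 and 0.0510 without miR-NC replicate 1. IFT88 was not called without miR-7 replicate 1 or miR-NC replicate 1 (0.137 to 0.207), nor IFT57 and IFT43 without miR-7 replicate 2 (0.0583 and 0.120). With the mean of probe sets IFT57 (0.63, adjusted p = 0.0727) and IFT43 (0.24, 0.398) did not pass and IFT80 changed by 0.81, nor did IFT43 pass without probe sets ending in _x_at or _s_at (0.44, 0.152).

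Of 5933 genes with at least 2 kept probe sets, 1051 had at least 1 called probe set. Genes with a called and a flat probe set, such as UBQLN4 and ATL3, were not counted. In 3 of the 1051, a probe set passed in each direction. For PNN they gave -0.77 and 0.76, for RFC5 -0.57 and 1.01, and for SSBP1 -0.49 and 1.88. Of 4647 kept probe sets with no single gene named, 125 were lower and 89 higher.

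A hypothesis for the genes higher with miR-7 is that the transfected microRNA competes with endogenous ones, whose targets may then rise. Known targets of let-7, miR-21 and the miR-17 family, 46 measured in all, gave 4 lower, 8 higher and a median of 0.05. The unadjusted camera p of the pooled list was 0.338 and the adjusted p 0.677. The let-7 list had 1 lower and 4 higher of 19, the miR-21 list 1 and 1 of 14, and the miR-17 family list 2 and 3 of 13. The pooled list passed in neither direction, so the hypothesis is neither borne out nor excluded.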
